A study of Homo sapiens with 12 samples.

How the data were processed

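Poly(A) RNA was captured on poly-T beads, fragmented and copied with random hexamers, per the labels, and 12 libraries were sequenced from CAL-27 and SCC-4 cells, 3 control and 3 SRSF1 knockdown libraries in each line. Whether the libraries keep the strand is not stated. The submitters' notes name HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.16.1 without giving the role or order of each, apart from DESeq2, which the design text gives for the differential test. The deposited table holds 1 count per gene and library as raw counts, per the file headers. It also holds deposited FPKM values, made by the authors, which were used only for a check. That check showed that the FPKM denominators follow totals scaled by DESeq2 size factors, to within 0.01%. For each line the authors gave a log2 fold change of knockdown over control and a p-value with its adjusted p-value. The gene length in bases is the authors' own. The table lists 59175 loci, of which 58395 are Ensembl genes and 780 unannotated loci, and 0 of its entries name no gene. The genome build is not given in the sources used here. Of 58275 Ensembl genes shared with GENCODE release 29, 98.7% have the same start and end to the base.

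Totals per library ranged from 26582867 to 29857748 counts. Poisson intervals and floors cover counting error only, as reads are not independent. Others cover spread over libraries or genes. The first principal component (82.7% of the variance) separated the lines and the second carried 6.9%. Replicate libraries differed from one another by 3.6 to 8.4 times the counting variance, so none is a copy of another. Library pairing by replicate number is open. Control and knockdown residuals of equal number correlated over genes at -0.007 to 0.029, yet blocking on it called more genes.

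Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr on the 4 groups (minimum count 10, minimum total count 15) were kept, 19816 in all. Libraries were scaled by TMM and a quasi-likelihood model with robust dispersion was fitted with 1 mean per cell line and arm and 8 residual degrees of freedom. Contrasts were knockdown minus control in each line, their average, and the SCC-4 effect minus the CAL-27 effect. The quasi-likelihood F test is 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a contrast. The study's own threshold of 1.5 on the log2 scale was counted separately. Standard errors were obtained from the F statistic and the log2 fold change. The biological coefficient of variation was 6.87%. CPM are scaled by the TMM factors. The overlap of the calls of both lines was compared with the number expected from their sizes by Fisher's exact test.

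Before the data were examined, 38 gene lists with 1267 distinct symbols were fixed, covering the lysosome, autophagy, splicing, stress responses, the cell cycle, metabolism, epithelial state and markers of immune cells, fibroblasts and endothelium. Of these symbols 1195 were tested. Each list was tested with camera (limma 3.58.1), which compares its members with all other genes, at a preset correlation of 0.01, and again with an estimated correlation. Adjusted p for lists is over the 38 lists of a contrast. Counts adjusted over the list alone apply the Benjamini-Hochberg correction to the members only. The direct test fry was also run.

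Genes to be named were chosen by a rule set at the same time, with SRSF1 first. In each line the rule took the 8 largest rises and 8 largest falls among called protein-coding genes with a usual symbol, at least 5 CPM in the higher arm and no overlap between the 3 control and 3 knockdown libraries. For both lines it took the 8 rises and 8 falls with the largest smaller change, and for the difference the 5 largest of each sign. In each list it took up to 4 called members with the smallest p in each line. It added LAMP1, LAMP2, CTSD, CTSB, TFEB, SQSTM1, MAP1LC3B, BECN1, ATG5, ATG7 and MTOR whatever their result, because the series title names the lysosome and autophagy. Not every gene taken by the rule is printed.

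In a simulated test 100 to 225 of 19405 genes were changed, far fewer than called here. At a planted fold of 1.5, recovery was 62.0% (CAL-27), 65.4% (SCC-4), 76.9% (average) and 50.0% (difference). At a fold of 2 it was 86.0, 83.3, 93.3 and 60.0%. False calls made up 8.8, 8.9, 7.7 and 10.7% of calls, above the nominal 5%. A planted list of 25 genes at a fold of 1.3 was called (adjusted p = 2.07e-28) and 0 other lists were. Mixed CAL-27 arms still called up to 11.

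The authors' table called 8906 genes in CAL-27 and 3748 in SCC-4 at an adjusted p under 0.05. Its log2 fold changes had r of 0.998 and 0.997 with those of edgeR across genes, and 8683 and 3533 genes were called by both. Past the study threshold the authors' table has 832 genes in CAL-27 and 27 in SCC-4, against 927 and 113 here, and 689 and 19 passed in both. The cause of this gap was not tested. Alternatives tried were DESeq2 size factors in the edgeR model, no filter beyond 1 count, at least 1 CPM in 3 libraries, the replicate number as a block, limma-voom, DESeq2 1.42.0, each line fitted alone, lists without shared genes, an estimated correlation, and leaving out each library in turn. Library totals with no scaling factor were added after the data were seen. The FPKM values were left out of all tests because counts are given.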

Results

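Messenger RNA was sequenced from CAL-27 and SCC-4, both established human tongue squamous carcinoma cell lines, after knockdown of SRSF1, a splicing factor of the SR protein family. The design text calls the groups stable but names siRNA, so the kind of construct is open. Each line had 3 control and 3 SRSF1 knockdown libraries, 12 in all. The controls are si-NC in the design text and have the genotype WT in the labels. They were taken as cells with a non-targeting construct, and if they were untreated cells each change would also hold any effect of the construct. The CAL-27 controls held 28665650, 26767225 and 28148626 counts and the CAL-27 knockdown libraries 29007513, 27823104 and 29180062. The SCC-4 controls held 26582867, 27369833 and 29857748 counts and the SCC-4 knockdown libraries 27285229, 27188505 and 27364880. Mitochondrial genes took 6.221 to 6.741% of counts in CAL-27 controls and 6.554 to 7.488% in the knockdown. In SCC-4 they took 5.985 to 6.290% and 7.018 to 7.498%. Levels are given as mean ± SD of CPM, counts scaled to the size of the library, over n = 3 libraries per group, and log2 fold changes, knockdown over control, as estimate ± standard error. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries.

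The first question was how far the targeted transcript fell. SRSF1 mRNA fell in both lines. In CAL-27 SRSF1 (ENSG00000136450, chromosome 17, 58003360 to 58007346, minus strand) went from 160.1 ± 4.04 to 112 ± 3.04 CPM, 29.8% lower (log2 fold change -0.51 ± 0.04, adjusted p = 2.97e-11). In SCC-4 it went from 186 ± 7.40 to 122 ± 4.30 CPM, 34.3% lower (log2 fold change -0.61 ± 0.04, adjusted p = 1.83e-11). The SCC-4 effect minus the CAL-27 effect was -0.10 ± 0.06 (adjusted p = 0.269, 95% interval -0.241 to 0.0489), a difference that did not pass the test. The genome build is not given in the sources used here. In the GENCODE annotation 60.7% of the exon bases of SRSF1 also lie in other annotated genes. Of the overlapping genes, the one with the most counts had 0.6% of the counts of SRSF1.

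**Figure D1:**
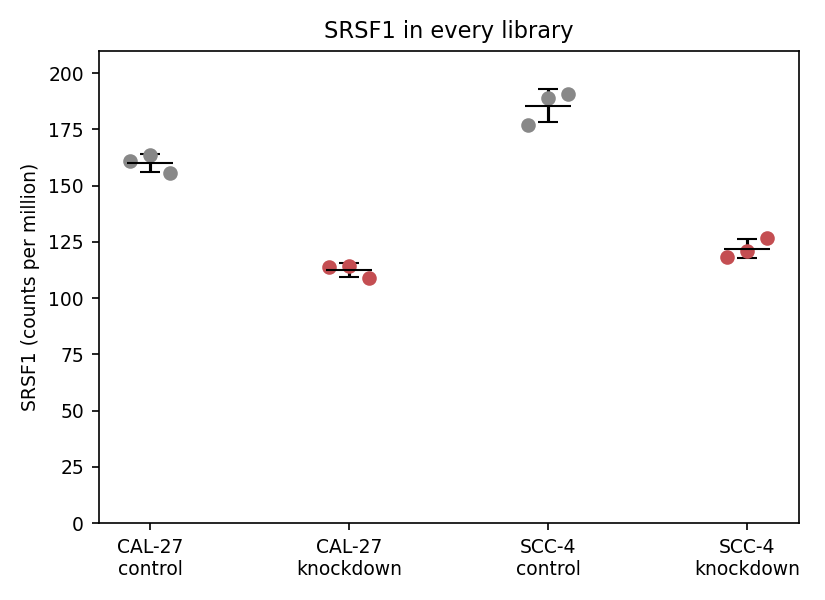
SRSF1 level in CPM for each library (points) in the control and knockdown groups of CAL-27 and SCC-4, with the group mean (bar) and SD (whiskers), n = 3 per group. The knockdown means of 112.5 and 122.0 CPM lie below the control means of 160.1 and 185.5 CPM.

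The CAL-27 comparison asked which transcripts changed after SRSF1 knockdown in that line. Most histone genes rose and most interferon-stimulated genes fell. HIST1H2BK (ENSG00000197903, chromosome 6, 27146418 to 27146798, minus strand), which encodes a core histone H2B, rose from 22.1 ± 0.483 to 158 ± 8.60 CPM (log2 fold change 2.83 ± 0.05, adjusted p = 2.06e-27). OASL (ENSG00000135114, chromosome 12, 121019111 to 121039242, minus strand), an antiviral protein induced by interferon, fell from 59.9 ± 2.15 to 8.82 ± 1.51 CPM (log2 fold change -2.76 ± 0.07, adjusted p = 1.83e-23). SERPINB2 (ENSG00000197632), an inhibitor of plasminogen activators, rose from 2.43 ± 0.232 to 28.7 ± 2.26 CPM (log2 fold change 3.56 ± 0.14). LOXL4 (ENSG00000138131), a lysyl oxidase that cross-links collagen, fell from 23.5 ± 0.449 to 2.02 ± 0.298 CPM (log2 fold change -3.54 ± 0.13). Of 19816 genes tested, 10315 changed, 5060 up and 5255 down. Of these, 343 rose and 584 fell beyond the study's threshold of 1.5 on the log2 scale, 927 in all. With at least 1 CPM required in 3 libraries, 558 passed that threshold.

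In CAL-27 poly(A) RNA 17 of 20 tested replication-dependent histones, which package newly made DNA, rose and 3 were not called. With adjustment over the list alone 18 rose, and camera adjusted p was 5.06e-38. The list median was 2.48 (log2). HIST1H2AC rose from 19.0 ± 1.41 to 107 ± 2.70 CPM and the linker histone gene HIST1H1C from 27.4 ± 1.47 to 85.5 ± 5.23 CPM (log2 fold changes 2.49 ± 0.05 and 1.64 ± 0.05). Of the interferon-stimulated genes, 38 of 46 tested members fell, 1 rose (HERC6) and 7 were not called, with 1 up and 38 down adjusted over the list alone and camera adjusted p = 5.34e-44. HERC6 was named after its values were seen, as were all other members named in brackets beside a count here and below. The median of the interferon-stimulated list was -0.90. OAS3, which makes the messenger that activates RNase L, fell from 350.2 ± 3.71 to 119 ± 5.24 CPM, and IFIT1, which binds viral RNA, fell from 69.8 ± 1.64 to 16.6 ± 0.987 CPM (log2 fold changes -1.56 ± 0.04 and -2.07 ± 0.06). RSAD2, which encodes viperin, fell from 13.4 ± 0.524 to 1.80 ± 0.338 CPM (log2 fold change -2.89 ± 0.13). Among immune cell markers CD74, a chaperone of class II antigen presentation, fell from 536 ± 9.88 to 259 ± 8.33 CPM and CD14, a receptor for bacterial lipopolysaccharide, fell from 16.7 ± 0.582 to 8.34 ± 1.21 CPM.

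Lysosomal genes in CAL-27 were tested as 4 lists, of hydrolases, V-ATPase subunits, biogenesis genes and membrane proteins. Among the lysosomal hydrolases, 31 of 53 tested members fell, 15 rose and 7 were not called, with 15 up and 33 down adjusted over the list alone and camera adjusted p = 0.000929. Lysosomal hydrolases had adjusted p = 0.0514 with an estimated correlation. GAA, which breaks down glycogen in lysosomes, fell from 214 ± 4.49 to 92.4 ± 2.78 CPM and MAN2B1, a lysosomal mannosidase, from 93.5 ± 3.14 to 50.2 ± 0.630 CPM (log2 fold changes -1.21 ± 0.05 and -0.90 ± 0.05). The protease gene CTSD fell from 283 ± 19.6 to 157 ± 17.6 CPM (log2 fold change -0.85 ± 0.07), and 52.7% of its exon bases also lie in another annotated gene. CTSB, another cathepsin, fell from 624 ± 14.1 to 561 ± 13.3 CPM (log2 fold change -0.15 ± 0.04). Among the V-ATPase subunits, which form the proton pump that acidifies lysosomes, 14 of 21 tested members rose, 2 fell (ATP6V0E2 and ATP6V1E2) and 5 were not called, with 15 up and 2 down adjusted over the list alone and camera adjusted p = 5.31e-05. ATP6V1H rose from 59.2 ± 1.06 to 93.9 ± 7.0 CPM and ATP6V0D1 from 85.6 ± 2.78 to 132 ± 9.41 CPM (log2 fold changes 0.67 ± 0.05 and 0.63 ± 0.05). Among the lysosome biogenesis and trafficking genes, 21 of 46 tested members rose, 8 fell and 17 were not called, with 21 up and 8 down adjusted over the list alone and camera adjusted p = 0.019. Lysosome biogenesis and trafficking genes had adjusted p = 0.0514 with an estimated correlation. SORT1, a sorting receptor for lysosomal cargo, rose from 35.6 ± 0.400 to 56.3 ± 3.90 CPM (log2 fold change 0.66 ± 0.06). Among the lysosomal membrane proteins, 17 of 41 tested members rose, 12 fell and 12 were not called, with 18 up and 12 down adjusted over the list alone and camera adjusted p = 0.966. LAMP1, a major lysosomal membrane glycoprotein, had a log2 fold change of 0.11 ± 0.04 (adjusted p = 0.0119), a call lost with library totals (adjusted p = 0.332), with no filter (0.0755) and without CAL-27 control replicate 3 (0.0651). LAMP2 was not called (-0.01 ± 0.04, adjusted p = 0.849). TFEB, a transcription factor of lysosomal genes, fell from 13.0 ± 0.702 to 9.88 ± 0.266 CPM (log2 fold change -0.39 ± 0.08).

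Among the autophagy machinery genes in CAL-27, 19 of 44 tested members rose, 8 fell and 17 were not called, with 19 up and 8 down adjusted over the list alone and camera adjusted p = 0.106. MAP1LC3B, whose product marks autophagosome membranes, rose from 91.6 ± 2.20 to 168 ± 7.82 CPM (log2 fold change 0.88 ± 0.05), and GABARAPL1, of the same family, fell from 107 ± 3.10 to 71.6 ± 3.96 CPM (log2 fold change -0.57 ± 0.05). Log2 fold changes were 0.26 ± 0.05 for BECN1 (adjusted p = 0.000117), 0.24 ± 0.05 for ATG5 (adjusted p = 0.000263) and -0.04 ± 0.08 for ATG7 (adjusted p = 0.677). Exons of BECN1 overlap those of PSME3 and exons of ATG7 those of VGLL4. Among the autophagy receptors, 9 of 21 tested members rose, 5 fell (CALCOCO1, FKBP8, OPTN, PHB2 and RTN3) and 7 were not called, with 9 up and 5 down adjusted over the list alone and camera adjusted p = 0.985. TAX1BP1, a receptor that links ubiquitin to autophagosomes, rose from 291 ± 15.3 to 386 ± 18 CPM (log2 fold change 0.41 ± 0.05). The receptor gene SQSTM1 differed widely between replicates, from 16.7 ± 1.77 to 75.7 ± 41.6 CPM (log2 fold change 2.18 ± 0.61, adjusted p = 0.0159). The SQSTM1 call was lost with limma-voom (0.0503) and without CAL-27 control replicate 1 (0.0532) or 2 (0.0536) or knockdown replicate 1 (0.0501) or 3 (0.0511). Among the MTOR pathway genes, 16 of 41 tested members rose, 8 fell and 17 were not called, with 16 up and 8 down adjusted over the list alone and camera adjusted p = 0.2. MTOR itself had a log2 fold change of 0.34 ± 0.05 (adjusted p = 8.71e-07), and FNIP1, a folliculin partner, rose from 54.4 ± 2.23 to 84.9 ± 3.54 CPM.

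Stress response lists came next in CAL-27. Among the unfolded protein response genes, 21 of 26 tested members rose, 1 fell (EDEM1) and 4 were not called, with 21 up and 1 down adjusted over the list alone and camera adjusted p = 3.20e-10. DNAJC3, an inhibitor of the kinase PERK, rose from 56.9 ± 1.59 to 113 ± 2.99 CPM, and HSPA5, the ER chaperone BiP, from 1138 ± 30.3 to 1737 ± 87.8 CPM (log2 fold changes 0.99 ± 0.05 and 0.61 ± 0.04). Among the oxidative stress (NRF2) genes, 15 of 28 tested members fell, 4 rose (KEAP1, ME1, NFE2L2 and UGDH) and 9 were not called, with 4 up and 15 down adjusted over the list alone and camera adjusted p = 3.10e-05. GCLC, which catalyses the first step of glutathione synthesis, fell from 128 ± 1.90 to 64.4 ± 2.66 CPM. TXNRD1, a thioredoxin reductase, fell from 575 ± 15.4 to 353 ± 14.3 CPM (log2 fold change -0.70 ± 0.04). Among the cholesterol biosynthesis genes, 19 of 30 tested members rose, 3 fell (HSD17B7, SREBF2 and TM7SF2) and 8 were not called, with 19 up and 3 down adjusted over the list alone and camera adjusted p = 0.000401. SCD, a fatty acid desaturase, rose from 426 ± 11.2 to 742 ± 25.5 CPM. Among the heat shock proteins, 8 of 19 tested members rose, 3 fell (FKBP4, HSF2 and HSPB1) and 8 were not called, with 8 up and 3 down adjusted over the list alone and camera adjusted p = 0.0229. Heat shock proteins had adjusted p = 0.263 with an estimated correlation. HSPA8, a constitutive HSP70 chaperone, rose from 1043 ± 48.5 to 1816 ± 96.0 CPM. Among the cytosolic ribosomal proteins, 52 of 74 tested members fell, 2 rose (RPL12 and RPL6) and 20 were not called, with 3 up and 53 down adjusted over the list alone and camera adjusted p = 3.54e-06. Cytosolic ribosomal proteins had adjusted p = 0.326 with an estimated correlation. RPS3 fell from 1565 ± 57.3 to 1059.6 ± 39.0 CPM. Among the G2/M and mitosis genes, 32 of 48 tested members fell, 6 rose and 10 were not called, with 6 up and 32 down adjusted over the list alone and camera adjusted p = 3.10e-05. G2/M and mitosis genes had adjusted p = 0.263 with an estimated correlation. CDC20, an activator of the anaphase-promoting complex, fell from 209.7 ± 4.12 to 146 ± 3.22 CPM. Among the mitochondrially encoded genes, 9 of 13 tested members rose and 4 were not called, with 10 up adjusted over the list alone and camera adjusted p = 0.00263. Mitochondrially encoded genes had adjusted p = 0.326 with an estimated correlation. MT-ND2, a subunit of respiratory complex I, rose from 1974 ± 93.3 to 3198 ± 252 CPM. The mitochondrial share of all counts overlapped between the 2 CAL-27 groups.

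Splicing genes were also tested in CAL-27: among the SR proteins and TRA2, 11 of 16 tested members rose, 1 fell (SRRM1) and 4 were not called, with 12 up and 1 down adjusted over the list alone and camera adjusted p = 0.011. SR proteins and TRA2 had adjusted p = 0.208 with an estimated correlation. SRSF6, another SR protein, rose from 152 ± 3.90 to 265 ± 7.91 CPM (log2 fold change 0.80 ± 0.04). Among the core spliceosome genes, 29 of 49 tested members rose, 9 fell and 11 were not called, with 30 up and 9 down adjusted over the list alone and camera adjusted p = 0.0131. Core spliceosome genes had adjusted p = 0.263 with an estimated correlation. SF3B3, a U2 snRNP protein, fell from 274 ± 4.99 to 186 ± 0.725 CPM and PRPF38A, a spliceosome activation factor, rose from 53.8 ± 1.3 to 86.9 ± 3.78 CPM. Among the genes with splicing regulated by SRSF1, 15 of 25 tested members rose, 6 fell and 4 were not called, with 15 up and 6 down adjusted over the list alone and camera adjusted p = 0.00516. Gene counts do not show splicing. BCL2L1 rose from 40.4 ± 0.414 to 88.6 ± 3.62 CPM, with 43.0% of its exon bases opposite an antisense gene. Among the p53 target genes, 16 of 32 tested members rose, 7 fell and 9 were not called, with 17 up and 8 down adjusted over the list alone and camera adjusted p = 0.0224. p53 target genes had adjusted p = 0.0678 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, rose from 63.1 ± 4.05 to 127 ± 3.60 CPM. Among the YAP and TEAD target genes, 10 of 21 tested members rose, 5 fell (ARHGEF17, CTGF, IGFBP3, NUAK2 and TGFB2) and 6 were not called, with 10 up and 5 down adjusted over the list alone and camera adjusted p = 0.0214. YAP and TEAD target genes had adjusted p = 0.089 with an estimated correlation. NT5E, the ectonucleotidase CD73, rose from 82.3 ± 2.57 to 315 ± 12.4 CPM and CTGF fell from 28.7 ± 2.60 to 10.4 ± 0.166 CPM. Among the immediate early genes, 14 of 33 tested members rose, 11 fell and 8 were not called, with 14 up and 11 down adjusted over the list alone and camera adjusted p = 0.038. Immediate early genes had adjusted p = 0.154 with an estimated correlation. PHLDA1 rose from 127 ± 2.85 to 337 ± 1.78 CPM and EGR1, a growth factor induced transcription factor, fell from 90.4 ± 3.81 to 40.4 ± 0.835 CPM.

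The remaining lists were not called in CAL-27. Among the SR protein kinases and phosphatases, 6 of 13 tested members rose, 2 fell (CLK1 and CLK3) and 5 were not called, with 6 up and 2 down adjusted over the list alone and camera adjusted p = 0.127. Among the hnRNP proteins, 9 of 25 tested members rose, 5 fell (HNRNPA1, HNRNPA3, HNRNPF, HNRNPH3 and PTBP1) and 11 were not called, with 9 up and 5 down adjusted over the list alone and camera adjusted p = 0.368. Among the nonsense-mediated decay factors, 11 of 19 tested members rose, 3 fell (SMG6, SMG9 and UPF3A) and 5 were not called, with 11 up and 4 down adjusted over the list alone and camera adjusted p = 0.138. Among the transcripts commonly used as NMD reporters, 9 of 23 tested members rose, 8 fell and 6 were not called, with 9 up and 8 down adjusted over the list alone and camera adjusted p = 0.178. Among the G1/S and DNA replication genes, 19 of 46 tested members fell, 9 rose and 18 were not called, with 10 up and 19 down adjusted over the list alone and camera adjusted p = 0.0824. Among the apoptosis regulators, 17 of 36 tested members rose, 9 fell and 10 were not called, with 17 up and 9 down adjusted over the list alone and camera adjusted p = 0.0889. Among the integrated stress response genes, 18 of 39 tested members rose, 13 fell and 8 were not called, with 18 up and 13 down adjusted over the list alone and camera adjusted p = 0.136. Among the glycolysis and hypoxia genes, 14 of 37 tested members rose, 14 fell and 9 were not called, with 14 up and 14 down adjusted over the list alone and camera adjusted p = 0.564. Among the nuclear oxidative phosphorylation genes, 25 of 66 tested members rose, 16 fell and 25 were not called, with 25 up and 16 down adjusted over the list alone and camera adjusted p = 0.393. Among the inflammatory cytokines and NF-kappaB genes, 20 of 42 tested members rose, 12 fell and 10 were not called, with 23 up and 12 down adjusted over the list alone and camera adjusted p = 0.952. Among the epithelial-mesenchymal transition genes, 19 of 42 tested members rose, 19 fell and 4 were not called, with 19 up and 19 down adjusted over the list alone and camera adjusted p = 0.127. Among the basal keratinocyte markers, 12 of 30 tested members fell, 11 rose and 7 were not called, with 12 up and 13 down adjusted over the list alone and camera adjusted p = 0.713. Among the squamous differentiation genes, 10 of 37 tested members rose, 9 fell and 18 were not called, with 10 up and 9 down adjusted over the list alone and camera adjusted p = 0.817. Among the immune cell markers, 2 of 7 tested members fell (CD14 and CD74), 1 rose (CSF1R) and 4 were not called, with 1 up and 2 down adjusted over the list alone and camera adjusted p = 0.122. Among the fibroblast markers, 6 of 13 tested members fell, 1 rose (FAP) and 6 were not called, with 1 up and 6 down adjusted over the list alone and camera adjusted p = 0.082. Among the endothelial markers, 3 of 8 tested members fell (CDH5, EGFL7 and VWF) and 5 were not called, with 3 down adjusted over the list alone and camera adjusted p = 0.292. Named members with large changes were LCN2, an iron-trapping protein (from 321 ± 9.13 to 71.3 ± 2.76 CPM), the growth factor gene CSF2 (from 9.13 ± 0.707 to 57.4 ± 0.165 CPM), and INHBA, a subunit of activin (from 177 ± 10.9 to 622 ± 19.3 CPM). KRT15, a keratin of basal cells, fell from 253 ± 1.53 to 108 ± 2.89 CPM, and COL17A1, a hemidesmosome collagen, rose from 849 ± 14 to 1789 ± 66.5 CPM. FBLN1, an extracellular matrix protein, fell from 83.9 ± 1.33 to 29.5 ± 3.36 CPM. The median and mean of the inflammatory and squamous lists and of the autophagy receptors were above 0 and the test pointed down. For the epithelial-mesenchymal list the median and mean were below 0 and the test pointed up, and for lysosomal membrane proteins the median was above 0 with the mean and the test below. Of the 18 lists called in CAL-27, 7 held with an estimated correlation. Calls also ended elsewhere: immediate early genes in 8 of 22 settings (up to 0.272), among them without CAL-27 control replicate 3 (adjusted p = 0.0695), YAP targets in 5 (up to 0.149), p53 targets in 4 (up to 0.373), heat shock proteins in 3, the core spliceosome list and lysosome biogenesis with library totals (each 0.0566), and the SRSF1 splicing list without genes shared with other lists (0.123).

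**Figure D2:**
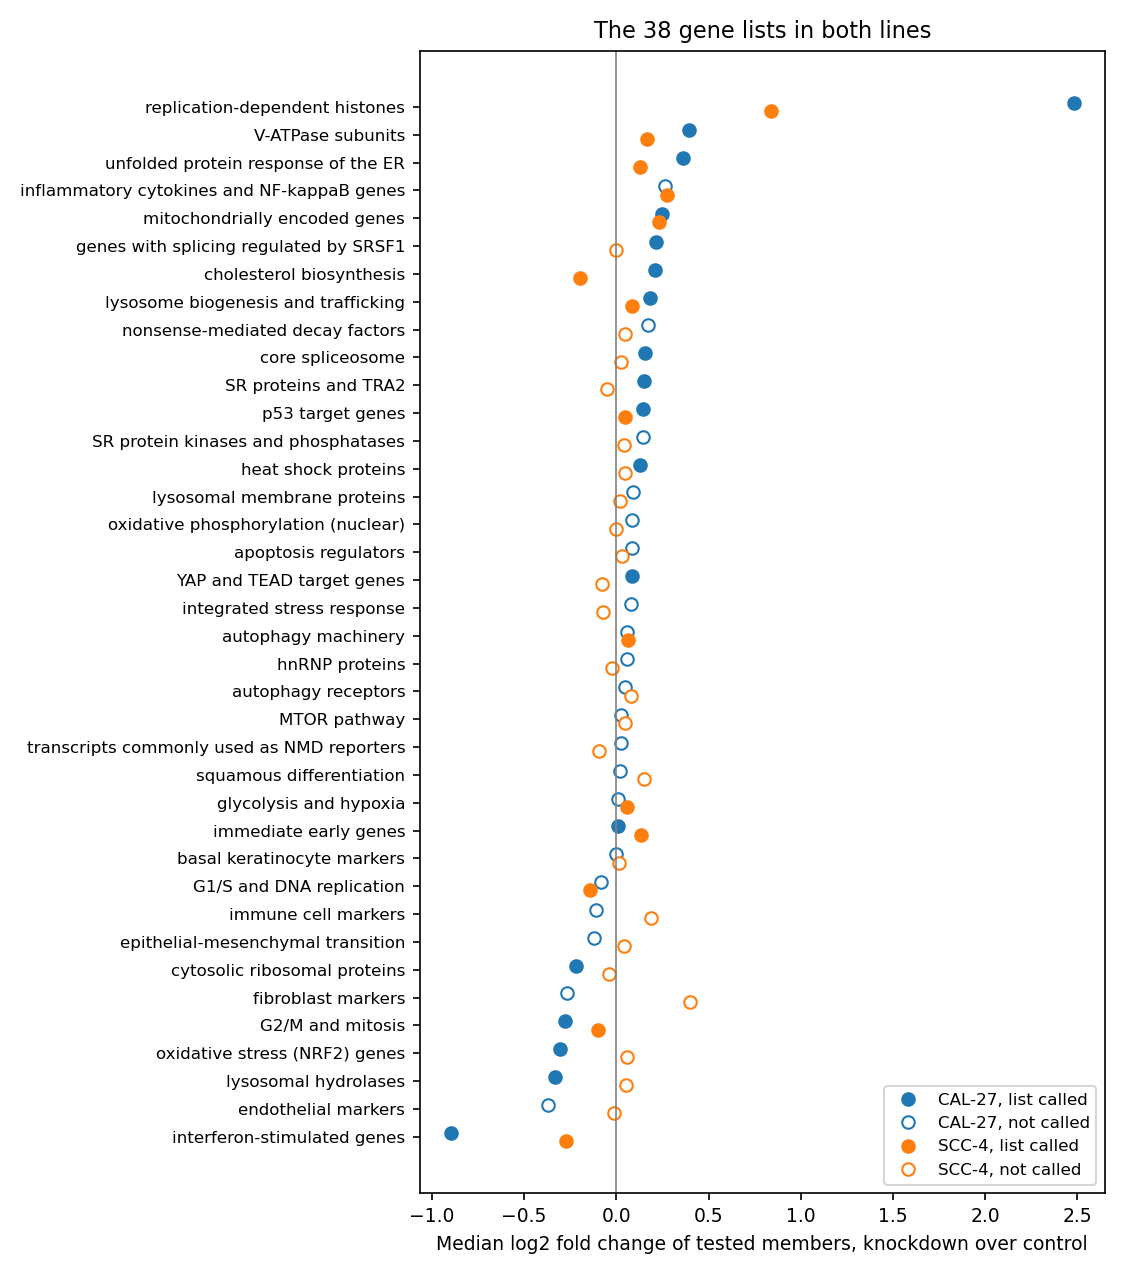
Median log2 fold change (x axis) of the tested members of each of the 38 gene lists (y axis) in CAL-27 (blue) and SCC-4 (orange), filled where camera called the list and open where it did not. Histones have the highest medians, 2.48 and 0.84, and interferon-stimulated genes medians of -0.90 and -0.27.

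The SCC-4 comparison asked the same question in the second line. Camera called histone and inflammatory genes up and interferon-stimulated and cholesterol genes down, with the counts of members given below. CPA4 (ENSG00000128510, chromosome 7, 130293134 to 130324180, plus strand), a carboxypeptidase, rose from 20.3 ± 0.351 to 57.2 ± 1.74 CPM (log2 fold change 1.50 ± 0.07, adjusted p = 6.95e-17). HIST1H4H, which encodes a core histone H4, rose from 20.2 ± 1.99 to 44.4 ± 0.133 CPM (log2 fold change 1.13 ± 0.07, adjusted p = 1.10e-12). SH2D2A, a T cell adaptor protein, fell from 22.4 ± 2.71 to 10.9 ± 0.761 CPM (log2 fold change -1.04 ± 0.11, adjusted p = 1.34e-08), and ACOX3, a peroxisomal oxidase, fell from 11.5 ± 0.584 to 6.11 ± 0.207 CPM (log2 fold change -0.92 ± 0.12). Of 19816 genes, 4438 changed in SCC-4, 2217 up and 2221 down. Beyond the threshold of 1.5 there were 113, of which 80 rose and 33 fell. The authors' own table has 27, of which 17 rose and 10 fell, and 19 passed in both. In place of the 113 genes found here, 56 passed with at least 1 CPM in 3 libraries, 50 with DESeq2 and 61 with SCC-4 fitted alone.

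Among the replication-dependent histones in SCC-4, 19 of 20 tested members rose and 1 was not called, with 19 up and 1 down adjusted over the list alone and camera adjusted p = 7.65e-36. HIST1H2BK rose from 111 ± 1.77 to 199 ± 8.66 CPM and HIST1H1C from 68.5 ± 1.61 to 123 ± 1.73 CPM (log2 fold changes 0.84 ± 0.05 and 0.84 ± 0.05). Of the interferon-stimulated genes in SCC-4, 24 of 46 tested members fell and 22 were not called, with 26 down adjusted over the list alone and camera adjusted p = 1.97e-15. OASL fell from 183 ± 2.85 to 116 ± 3.79 CPM, OAS3 from 412 ± 5.24 to 322 ± 4.41 CPM and IFIT3 from 198 ± 7.75 to 152 ± 1.48 CPM (log2 fold changes -0.65 ± 0.06, -0.36 ± 0.04 and -0.39 ± 0.04). Among the inflammatory cytokines and NF-kappaB genes, 19 of 42 tested members rose, 7 fell and 16 were not called, with 20 up and 9 down adjusted over the list alone and camera adjusted p = 1.39e-06. TNFAIP2, a gene induced by TNF, rose from 152 ± 3.93 to 255 ± 6.47 CPM, and ICAM1, an adhesion molecule for leukocytes, from 36.2 ± 1.82 to 55.2 ± 2.00 CPM (log2 fold changes 0.75 ± 0.04 and 0.61 ± 0.05). MMP1, a collagenase on the same list, fell from 431 ± 8.35 to 296 ± 4.76 CPM. Among the cholesterol biosynthesis genes, 17 of 30 tested members fell, 2 rose (ELOVL6 and SC5D) and 11 were not called, with 2 up and 19 down adjusted over the list alone and camera adjusted p = 1.52e-06. SREBF2, the transcription factor of sterol synthesis, fell from 273 ± 6.34 to 209.6 ± 1.38 CPM and FASN, fatty acid synthase, from 457 ± 29.8 to 379 ± 18.1 CPM (log2 fold changes -0.38 ± 0.04 and -0.27 ± 0.05). Among the unfolded protein response genes, 12 of 26 tested members rose and 14 were not called, with 13 up adjusted over the list alone and camera adjusted p = 0.000119. HSPA5 rose from 1077 ± 4.48 to 1235 ± 17.4 CPM and CALR, another ER chaperone, from 938 ± 30.3 to 1095 ± 44.9 CPM.

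Lysosomal genes were tested in SCC-4 as the same 4 lists: among the lysosome biogenesis and trafficking genes, 13 of 46 tested members rose, 5 fell (AP3D1, GGA1, GGA3, M6PR and VPS35) and 28 were not called, with 13 up and 7 down adjusted over the list alone and camera adjusted p = 0.00371. SORT1 rose from 16.1 ± 0.904 to 29.3 ± 0.667 CPM, and GNPTAB, which makes the mannose phosphate tag of lysosomal enzymes, from 71.1 ± 1.77 to 92.0 ± 3.20 CPM (log2 fold changes 0.87 ± 0.07 and 0.37 ± 0.05). Among the V-ATPase subunits, 9 of 21 tested members rose, 1 fell (ATP6V1E2) and 11 were not called, with 9 up and 1 down adjusted over the list alone and camera adjusted p = 0.00371. ATP6V1B2 rose from 49.0 ± 0.558 to 64.5 ± 1.85 CPM (log2 fold change 0.40 ± 0.05). Among the lysosomal hydrolases, 14 of 53 tested members rose, 9 fell and 30 were not called, with 16 up and 10 down adjusted over the list alone and camera adjusted p = 0.179. CTSC, an activator of serine proteases, rose from 97.7 ± 2.49 to 144 ± 4.68 CPM, and GAA fell from 92.6 ± 5.38 to 73.0 ± 3.45 CPM (log2 fold changes 0.56 ± 0.04 and -0.34 ± 0.05). CTSD was not called (0.11 ± 0.07, adjusted p = 0.306), and the call of CTSB (0.13 ± 0.04, adjusted p = 0.0163) was lost without SCC-4 control replicate 2 (0.108) or knockdown replicate 1 (0.101). Among the lysosomal membrane proteins, 10 of 41 tested members rose, 9 fell and 22 were not called, with 11 up and 11 down adjusted over the list alone and camera adjusted p = 0.846. LAMP1 rose from 508 ± 4.64 to 564 ± 3.88 CPM and LAMP2 from 217 ± 9.72 to 254 ± 13.7 CPM (log2 fold changes 0.15 ± 0.04 and 0.23 ± 0.04). TFEB was not called (0.08 ± 0.07, adjusted p = 0.485). Among the autophagy machinery genes, 12 of 44 tested members rose, 4 fell (ATG101, ATG16L2, ATG7 and ULK2) and 28 were not called, with 14 up and 5 down adjusted over the list alone and camera adjusted p = 0.013. Autophagy machinery genes had adjusted p = 0.118 with an estimated correlation. MAP1LC3B rose from 84.6 ± 3.03 to 104 ± 5.06 CPM, and PIK3C3, the lipid kinase that starts autophagosome formation, from 16.0 ± 0.367 to 21.9 ± 1.13 CPM (log2 fold changes 0.30 ± 0.05 and 0.45 ± 0.07). Log2 fold changes were 0.08 ± 0.05 for BECN1 (adjusted p = 0.324) and -0.27 ± 0.08 for ATG7 (adjusted p = 0.0156), and ATG5 was not called (adjusted p = 0.984).

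Among the autophagy receptors in SCC-4, 6 of 21 tested members rose, 5 fell (FKBP8, NUFIP1, OPTN, PHB2 and TEX264) and 10 were not called, with 7 up and 5 down adjusted over the list alone and camera adjusted p = 0.255. BNIP3, a receptor for mitochondrial autophagy, rose from 49.9 ± 1.13 to 68.0 ± 4.01 CPM (log2 fold change 0.45 ± 0.05), and SQSTM1 was not called (1.12 ± 0.60, adjusted p = 0.244). Among the MTOR pathway genes, 10 of 41 tested members rose, 5 fell (AKT1, AKT2, EIF4EBP1, MLST8 and NPRL3) and 26 were not called, with 11 up and 5 down adjusted over the list alone and camera adjusted p = 0.117. RPS6KB1, the S6 kinase downstream of MTOR, rose from 34.0 ± 1.38 to 44.9 ± 0.167 CPM. MTOR had a log2 fold change of 0.15 ± 0.05 (adjusted p = 0.0299), not called with library totals (0.0903) or without SCC-4 control replicate 1 (0.0922) or 3 (0.0935) or knockdown replicate 1 (0.159) or 3 (0.0667). The ATG7 call was lost without SCC-4 control replicate 1 (0.0522) or 3 (0.0551) and without knockdown replicate 1 (0.0605) or 3 (0.0652).

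Among the mitochondrially encoded genes in SCC-4, where the mitochondrial share of counts was higher in each knockdown library than in each control, 9 of 13 tested members rose and 4 were not called, with 10 up adjusted over the list alone and camera adjusted p = 1.34e-10. Mitochondrially encoded genes had adjusted p = 0.0885 with an estimated correlation. MT-CO3, a subunit of cytochrome c oxidase, rose from 3699.6 ± 165 to 5024 ± 262 CPM. Among the G1/S and DNA replication genes, 21 of 46 tested members fell, 2 rose (among them CCNE1) and 23 were not called, with 2 up and 25 down adjusted over the list alone and camera adjusted p = 9.22e-07. G1/S and DNA replication genes had adjusted p = 0.0829 with an estimated correlation. RPA1, which coats single-stranded DNA, fell from 150.2 ± 4.79 to 112 ± 3.94 CPM and POLA2, a subunit of DNA polymerase alpha, from 63.5 ± 2.55 to 48.4 ± 1.78 CPM. Among the G2/M and mitosis genes, 12 of 48 tested members fell, 1 rose (ECT2) and 35 were not called, with 1 up and 14 down adjusted over the list alone and camera adjusted p = 0.00696. G2/M and mitosis genes had adjusted p = 0.57 with an estimated correlation. AURKB, a mitotic kinase, fell from 55.2 ± 0.352 to 44.0 ± 0.967 CPM. The G2/M call ended without SCC-4 control replicate 3 (adjusted p = 0.112). Among the glycolysis and hypoxia genes, 14 of 37 tested members rose, 6 fell and 17 were not called, with 14 up and 7 down adjusted over the list alone and camera adjusted p = 0.00349. Glycolysis and hypoxia genes had adjusted p = 0.118 with an estimated correlation. ADM, a vasodilator peptide induced by hypoxia, rose from 133 ± 8.17 to 195 ± 2.39 CPM. Among the immediate early genes, 13 of 33 tested members rose, 2 fell (KLF4 and NR4A1) and 18 were not called, with 13 up and 2 down adjusted over the list alone and camera adjusted p = 0.00873. Immediate early genes had adjusted p = 0.0829 with an estimated correlation. JUNB rose from 328 ± 23.2 to 445 ± 11.8 CPM and KLF4, also an epithelial differentiation factor, fell from 214 ± 5.91 to 149.9 ± 4.0 CPM. Among the p53 target genes, 9 of 32 tested members rose, 3 fell (CCNG1, DDB2 and XPC) and 20 were not called, with 9 up and 5 down adjusted over the list alone and camera adjusted p = 0.0355. p53 target genes had adjusted p = 0.0829 with an estimated correlation. ZMAT3 rose from 25.5 ± 1.88 to 38.9 ± 1.18 CPM and the DNA repair gene DDB2 fell from 70.5 ± 2.13 to 52.7 ± 2.18 CPM. The p53 call ended in 9 of 22 settings (up to 0.714), including without SCC-4 knockdown replicate 1 (0.0502), and the immediate early call without genes shared with other lists (0.0522).

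The remaining lists were not called in SCC-4. Among the SR proteins and TRA2, 5 of 16 tested members rose (SON, SREK1, SRRM2, SRSF6 and SRSF8), 4 fell (SRRM1, SRSF7, TRA2A and TRA2B) and 7 were not called, with 6 up and 5 down adjusted over the list alone and camera adjusted p = 0.825. Among the core spliceosome genes, 9 of 49 tested members rose, 5 fell (SF3B3, SNRPA1, SNRPB, SNRPD2 and U2AF2) and 35 were not called, with 9 up and 5 down adjusted over the list alone and camera adjusted p = 0.521. Among the genes with splicing regulated by SRSF1, 5 of 25 tested members rose (among them BCL2L11, EXOC1, RAC1 and RPS6KB1), 5 fell (BIN1, CCND1, ENG, LMNA and MCL1) and 15 were not called, with 5 up and 5 down adjusted over the list alone and camera adjusted p = 0.846. Among the SR protein kinases and phosphatases, 4 of 13 tested members rose (DYRK1A, PPP1CB, TNPO3 and TOP1), 1 fell (CLK3) and 8 were not called, with 4 up and 1 down adjusted over the list alone and camera adjusted p = 0.283. Among the hnRNP proteins, 4 of 25 tested members fell (HNRNPA3, HNRNPDL, HNRNPH3 and PTBP1), 2 rose (HNRNPH2 and HNRNPUL2) and 19 were not called, with 2 up and 4 down adjusted over the list alone and camera adjusted p = 0.363. Among the nonsense-mediated decay factors, 5 of 19 tested members rose (NBAS, PNRC2, RBM8A, SMG8 and UPF3B), 4 fell (SMG6, SMG9, UPF1 and UPF3A) and 10 were not called, with 6 up and 4 down adjusted over the list alone and camera adjusted p = 0.535. Among the transcripts commonly used as NMD reporters, 4 of 23 tested members fell (ATF5, GADD45A, SNHG15 and UPP1), 3 rose (ATF3, CDKN1A and CHAC1) and 16 were not called, with 3 up and 4 down adjusted over the list alone and camera adjusted p = 0.297. Among the cytosolic ribosomal proteins, 11 of 74 tested members fell, 2 rose (RPL12 and RPL23A) and 61 were not called, with 2 up and 11 down adjusted over the list alone and camera adjusted p = 0.143. Among the oxidative stress (NRF2) genes, 7 of 28 tested members rose, 4 fell (AKR1C1, SLC7A11, TKT and TXNRD1) and 17 were not called, with 9 up and 5 down adjusted over the list alone and camera adjusted p = 0.117. Among the heat shock proteins, 4 of 19 tested members rose (CRYAB, HSP90AA1, HSPB1 and HSPD1), 2 fell (HSF2 and HSPH1) and 13 were not called, with 4 up and 2 down adjusted over the list alone and camera adjusted p = 0.265. Among the integrated stress response genes, 11 of 39 tested members fell, 7 rose and 21 were not called, with 8 up and 13 down adjusted over the list alone and camera adjusted p = 0.317. Among the apoptosis regulators, 12 of 36 tested members rose, 5 fell (BAK1, BCL2L2, BOK, MCL1 and PMAIP1) and 19 were not called, with 12 up and 8 down adjusted over the list alone and camera adjusted p = 0.7. Among the YAP and TEAD target genes, 7 of 21 tested members fell, 3 rose (AMOTL2, ASAP1 and F3) and 11 were not called, with 4 up and 9 down adjusted over the list alone and camera adjusted p = 0.142. Among the nuclear oxidative phosphorylation genes, 6 of 66 tested members fell, 3 rose (NDUFA2, NDUFC2 and UQCRB) and 57 were not called, with 3 up and 5 down adjusted over the list alone and camera adjusted p = 0.846. Among the epithelial-mesenchymal transition genes, 10 of 42 tested members rose, 8 fell and 24 were not called, with 10 up and 8 down adjusted over the list alone and camera adjusted p = 0.283. Among the basal keratinocyte markers, 6 of 30 tested members rose, 6 fell and 18 were not called, with 6 up and 6 down adjusted over the list alone and camera adjusted p = 0.467. Among the squamous differentiation genes, 10 of 37 tested members rose, 5 fell (DSC2, EVPL, KLK10, LYPD3 and PPL) and 22 were not called, with 10 up and 5 down adjusted over the list alone and camera adjusted p = 0.197. Among the immune cell markers, 1 of 7 tested members rose (ITGAX) and 6 were not called, with none called when adjusted over the list alone and camera adjusted p = 0.467. Among the fibroblast markers, 2 of 13 tested members fell (COL1A1 and FBLN1), 1 rose (LUM) and 10 were not called, with 2 up and 2 down adjusted over the list alone and camera adjusted p = 0.521. Among the endothelial markers, 8 of 8 tested members were not called, with none called when adjusted over the list alone and camera adjusted p = 0.632. SRSF7, another SR protein, fell from 124 ± 1.71 to 101 ± 2.65 CPM, and AXL, a receptor tyrosine kinase, fell from 149.5 ± 8.79 to 103 ± 1.08 CPM. KRT13, a keratin of suprabasal mucosa, rose from 185 ± 8.22 to 259.7 ± 12.1 CPM, and PPL, the cornified envelope protein periplakin, fell from 204 ± 10.6 to 143 ± 6.11 CPM. The median of the SRSF1 splicing list was above 0 with its mean below, the median of the lysosomal membrane list above 0 with its mean below, and the median of the endothelial list below 0 with its mean above. Of the 14 lists called in SCC-4, 7 held with an estimated correlation.

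Of the members in brackets above that the naming rule also took, some lost their call in other settings, given as their number and the highest adjusted p with the library of that line then left out. In CAL-27 these were CSF1R in 1 (0.0682, without knockdown 1) and OPTN in 2 (0.13, without knockdown 1). In SCC-4 they were CHAC1 in 2 (0.0804, without knockdown 3), CLK3 in 1 (0.0509, without control 2), COL1A1 in 10 (0.199, without knockdown 2), FBLN1 in 4 (0.0772, without knockdown 2), HNRNPUL2 in 1 (0.0523, without control 2), HSPD1 in 4 (0.0824, without knockdown 3), HSPH1 in 13 (0.219, without control 3) and ITGAX in 7 (0.222, without control 2). They were also LUM in 6 (0.175, without knockdown 2), LYPD3 in 3 (0.22, without control 1), PPP1CB in 2 (0.0944, without knockdown 3), SMG6 in 5 (0.106, without knockdown 2), SON in 6 (0.172, without control 1), SREK1 in 4 (0.148, without knockdown 3) and SRSF8 in 5 (0.174, without control 2).

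The next comparison asked which changes the lines shared. HIST1H2BK, SORT1, MAP1LC3B and CPA4 rose in both lines, and OASL, GAA and RPA1 fell in both. CPA4 rose by 1.60 ± 0.07 in CAL-27 and 1.50 ± 0.07 in SCC-4 on the log2 scale, and SEC31B, a COPII coat protein, by 0.86 ± 0.11 and 1.14 ± 0.09. ENTPD3, an ectonucleotidase, rose by 1.41 ± 0.11 and 0.86 ± 0.11. PIGV, an enzyme of GPI anchor synthesis, had log2 fold changes of -1.08 ± 0.07 and -0.74 ± 0.07. The zinc finger genes ZNF517 (-1.60 ± 0.15 and -0.93 ± 0.15) and ZNF548 (-0.79 ± 0.10 and -0.82 ± 0.10) also fell in both lines. Of the 20 tested histone genes, 17 rose in both lines, and of the 46 interferon-stimulated genes 22 fell in both. Among the 26 genes of the unfolded protein response 12 rose in both lines, and 7 of the 13 mitochondrially encoded genes did. For the V-ATPase, 8 of 21 subunits rose in both lines and 1 (ATP6V1E2, whose exons overlap those of RHOQ) fell. Of 44 autophagy machinery genes 9 rose in both and 2 (ATG16L2 and ULK2) fell in both, and of 46 genes of lysosome biogenesis 10 rose and 2 (GGA1 and M6PR) fell.

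Over all genes, 1515 rose in both lines against 566.1 expected from the counts of each line (odds ratio 8.55), and 1477 fell in both against 589.0 expected (odds ratio 7.26). Of 3444 genes called in both lines, 2992 (86.9%) changed in the same direction. Across 15150 genes at 1 CPM or more the log2 fold changes of the lines had a Pearson r of 0.317 and a Spearman rho of 0.428, and genes are not independent replicates. Among genes called in both lines the slope of SCC-4 on CAL-27 was 0.372. The effect averaged over the lines was called for 9585 genes, 4711 up and 4874 down. Averaged over the lines, 18 lists were called and 5 held with an estimated correlation, namely histones (adjusted p = 8.32e-06 with that correlation), interferon-stimulated genes (0.000283), the unfolded protein response (0.00435), V-ATPase subunits (0.012) and lysosome biogenesis (0.0375). With at least 1 CPM in 3 libraries 11 lists were called for the average.

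**Figure D3:**
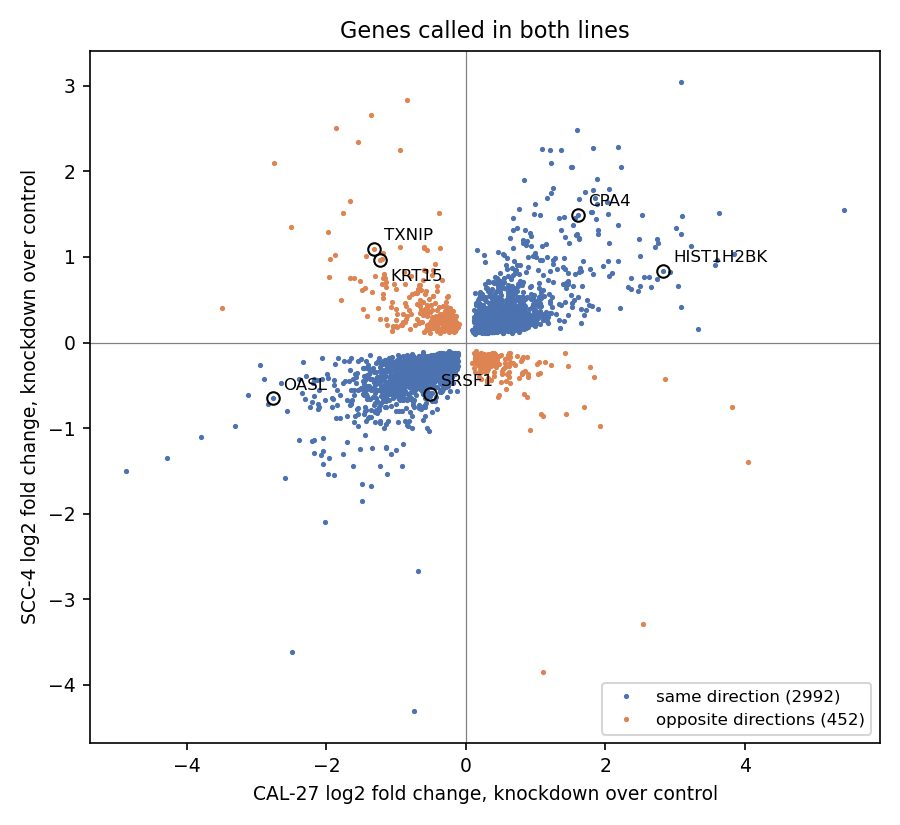
Log2 fold change in CAL-27 (x axis) against SCC-4 (y axis) for the 3444 genes called in both lines, each point 1 gene. Of these, 2992 lie in the quadrants of the same direction and 452 in those of opposite direction, where TXNIP and KRT15 are labelled.

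The last comparison asked which effects differed between the lines, as the SCC-4 effect minus the CAL-27 effect. Most differences came with the larger change in CAL-27, and some genes went opposite ways. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600, minus strand), which binds thioredoxin and limits glucose uptake, fell from 1712 ± 38.1 to 687 ± 10.6 CPM in CAL-27 and rose from 38.2 ± 1.82 to 81.7 ± 3.24 CPM in SCC-4 (difference 2.41 ± 0.06, adjusted p = 1.45e-23). KRT15 fell in CAL-27 (log2 fold change -1.22 ± 0.04) and rose in SCC-4 (0.96 ± 0.04, difference 2.19 ± 0.06, adjusted p = 4.97e-23). NQO1, a quinone reductase, fell in CAL-27 and rose in SCC-4 (difference 0.71 ± 0.06, adjusted p = 1.66e-11), and AXL rose in CAL-27 and fell in SCC-4 (difference -1.11 ± 0.06, adjusted p = 8.48e-15). The difference was called for 6239 genes, 3032 positive and 3207 negative. With library totals most were positive, 3399 against 2719. In 5486 of the 6239 (87.9%) the absolute change was larger in CAL-27. The 6239 genes comprise 1306 called in both lines in the same direction, 452 called in opposite directions, 3860 called in CAL-27 alone, 409 called in SCC-4 alone and 212 called in neither. By the rule for named genes LOXL4, UGT1A1, ENPP5, RCSD1 and SELENOP had the largest positive differences and SERPINB2, EVC2, NAPRT, ABCC9 and G0S2 the largest negative ones. The LOXL4 difference was 3.28 ± 0.17 (adjusted p = 1.31e-15) and that of SERPINB2 -3.69 ± 0.20 (adjusted p = 1.82e-15). ABCC9, a sulfonylurea receptor, went from 0.151 ± 0.0870 to 1.50 ± 0.0709 CPM in CAL-27 and from 20.1 ± 0.855 to 21.1 ± 1.03 CPM in SCC-4 (difference -3.22 ± 0.28). The SELENOP, EVC2 and NAPRT differences were lost in 7, 15 and 13 other settings, with adjusted p up to 0.289 for SELENOP without CAL-27 control replicate 3, 1 for EVC2 without CAL-27 knockdown replicate 1, and 0.223 for NAPRT with limma-voom.

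For the difference, among the replication-dependent histones, 16 of 20 tested members had the more negative effect in SCC-4, 1 the more positive one (HIST1H1B) and 3 were not called, with 1 up and 16 down adjusted over the list alone and camera adjusted p = 3.16e-24. Among the interferon-stimulated genes, 29 of 46 tested members had the more positive effect in SCC-4, 2 the more negative one (HERC6 and ISG20) and 15 were not called, with 30 up and 2 down adjusted over the list alone and camera adjusted p = 1.06e-31. Among the cholesterol biosynthesis genes, 22 of 30 tested members had the more negative effect in SCC-4, 1 the more positive one (TM7SF2) and 7 were not called, with 1 up and 23 down adjusted over the list alone and camera adjusted p = 3.44e-12. FASN had a difference of -0.48 ± 0.06. Among the oxidative stress (NRF2) genes, 16 of 28 tested members had the more positive effect in SCC-4, 4 the more negative one (KEAP1, OSGIN1, SLC7A11 and UGDH) and 8 were not called, with 17 up and 4 down adjusted over the list alone and camera adjusted p = 1.01e-09. GCLC had a difference of 1.19 ± 0.06. Among the unfolded protein response genes, 13 of 26 tested members had the more negative effect in SCC-4 and 13 were not called, with 14 down adjusted over the list alone and camera adjusted p = 6.80e-07. XBP1, a transcription factor of this response, had a difference of -0.94 ± 0.06. Among the lysosomal hydrolases, 30 of 53 tested members had the more positive effect in SCC-4, 6 the more negative one and 17 were not called, with 33 up and 8 down adjusted over the list alone and camera adjusted p = 1.18e-06. GAA had a difference of 0.87 ± 0.07, SCPEP1, a serine carboxypeptidase, 0.73 ± 0.06 and CTSD 0.96 ± 0.10. Among the V-ATPase subunits, 10 of 21 tested members had the more negative effect in SCC-4, 2 the more positive one (ATP6V0E2 and ATP6V1E2) and 9 were not called, with 2 up and 11 down adjusted over the list alone and camera adjusted p = 0.00295. Among the YAP and TEAD target genes, 11 of 21 tested members had the more negative effect in SCC-4, 4 the more positive one (AMOTL2, CTGF, IGFBP3 and TGFB2) and 6 were not called, with 5 up and 11 down adjusted over the list alone and camera adjusted p = 0.000268. AXL and NT5E, with differences of -1.11 ± 0.06 and -2.04 ± 0.06, rose in CAL-27. Among the genes with splicing regulated by SRSF1, 12 of 25 tested members had the more negative effect in SCC-4, 4 the more positive one (BCL2L11, ENG, MKNK2 and MYB) and 9 were not called, with 4 up and 14 down adjusted over the list alone and camera adjusted p = 0.00125. CD44, a hyaluronan receptor, had a difference of -0.71 ± 0.05. Among the inflammatory cytokines and NF-kappaB genes, 14 of 42 tested members had the more positive effect in SCC-4, 11 the more negative one and 17 were not called, with 15 up and 11 down adjusted over the list alone and camera adjusted p = 0.00811. TNFAIP2 had a difference of 1.93 ± 0.06. Of the bracketed members for the difference that the naming rule took, 2 lost their call in other settings, ATP6V1E2 in 1 (0.0525, without CAL-27 knockdown replicate 1) and PDGFRB in 1 (0.0986, without SCC-4 knockdown replicate 3). The inflammatory call was lost with limma-voom (adjusted p = 0.27) and with no filter (0.21).

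For the difference of the cytosolic ribosomal proteins, 39 of 74 tested members had the more positive effect in SCC-4 and 35 were not called, with 43 up and 3 down adjusted over the list alone and camera adjusted p = 6.93e-06. Cytosolic ribosomal proteins had adjusted p = 0.388 with an estimated correlation. Among the G2/M and mitosis genes, 23 of 48 tested members had the more positive effect in SCC-4, 4 the more negative one (ANLN, CENPE, CENPK and FOXM1) and 21 were not called, with 24 up and 4 down adjusted over the list alone and camera adjusted p = 0.00125. G2/M and mitosis genes had adjusted p = 0.388 with an estimated correlation. Among the SR proteins and TRA2, 9 of 16 tested members had the more negative effect in SCC-4 and 7 were not called, with 9 down adjusted over the list alone and camera adjusted p = 0.00173. SR proteins and TRA2 had adjusted p = 0.137 with an estimated correlation. Among the core spliceosome genes, 18 of 49 tested members had the more negative effect in SCC-4, 4 the more positive one (SF3A2, SF3B3, SNRPD2 and USP39) and 27 were not called, with 5 up and 20 down adjusted over the list alone and camera adjusted p = 0.0111. Core spliceosome genes had adjusted p = 0.285 with an estimated correlation. Among the heat shock proteins, 7 of 19 tested members had the more negative effect in SCC-4, 2 the more positive one (FKBP4 and HSPB1) and 10 were not called, with 2 up and 7 down adjusted over the list alone and camera adjusted p = 0.031. Heat shock proteins had adjusted p = 0.285 with an estimated correlation. Among the fibroblast markers, 5 of 13 tested members had the more positive effect in SCC-4 (COL1A2, COL3A1, FBLN1, PDGFRB and S100A4) and 8 were not called, with 5 up adjusted over the list alone and camera adjusted p = 0.031. Fibroblast markers had adjusted p = 0.108 with an estimated correlation. Among the integrated stress response genes, 16 of 39 tested members had the more negative effect in SCC-4, 8 the more positive one and 15 were not called, with 9 up and 18 down adjusted over the list alone and camera adjusted p = 0.0339. Integrated stress response genes had adjusted p = 0.285 with an estimated correlation. Among the transcripts commonly used as NMD reporters, 10 of 23 tested members had the more negative effect in SCC-4, 5 the more positive one (ASNS, EPB41L4A-AS1, GAS5, SNHG16 and ZFAS1) and 8 were not called, with 5 up and 10 down adjusted over the list alone and camera adjusted p = 0.031. Transcripts commonly used as NMD reporters had adjusted p = 0.264 with an estimated correlation. For the list integrated stress response, difference between lines, the call ended without CAL-27 control replicate 3 (0.0537), SCC-4 control replicate 1 (0.0691) or SCC-4 knockdown replicate 3 (0.0508). It also ended with library totals (0.0696), at least 1 CPM (0.0705), the replicate block (0.0711) and lists without shared genes (0.327). For the list transcripts commonly used as NMD reporters, difference between lines, the call ended without SCC-4 knockdown replicate 3 (0.0582), at 1 CPM (0.0597), with limma-voom (0.0979), with DESeq2 (0.0511) and with lists without shared genes (0.895). Of the 18 lists called for the difference, 10 held with an estimated correlation, and the other 20 lists had adjusted p from 0.0949 (apoptosis regulators) to 0.874 (lysosomal membrane proteins). Median, mean and test differed in sign for the epithelial-mesenchymal, immediate early, apoptosis, basal keratinocyte, squamous, MTOR, autophagy receptor and mitochondrially encoded lists, none of them called.

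**Figure D4:**
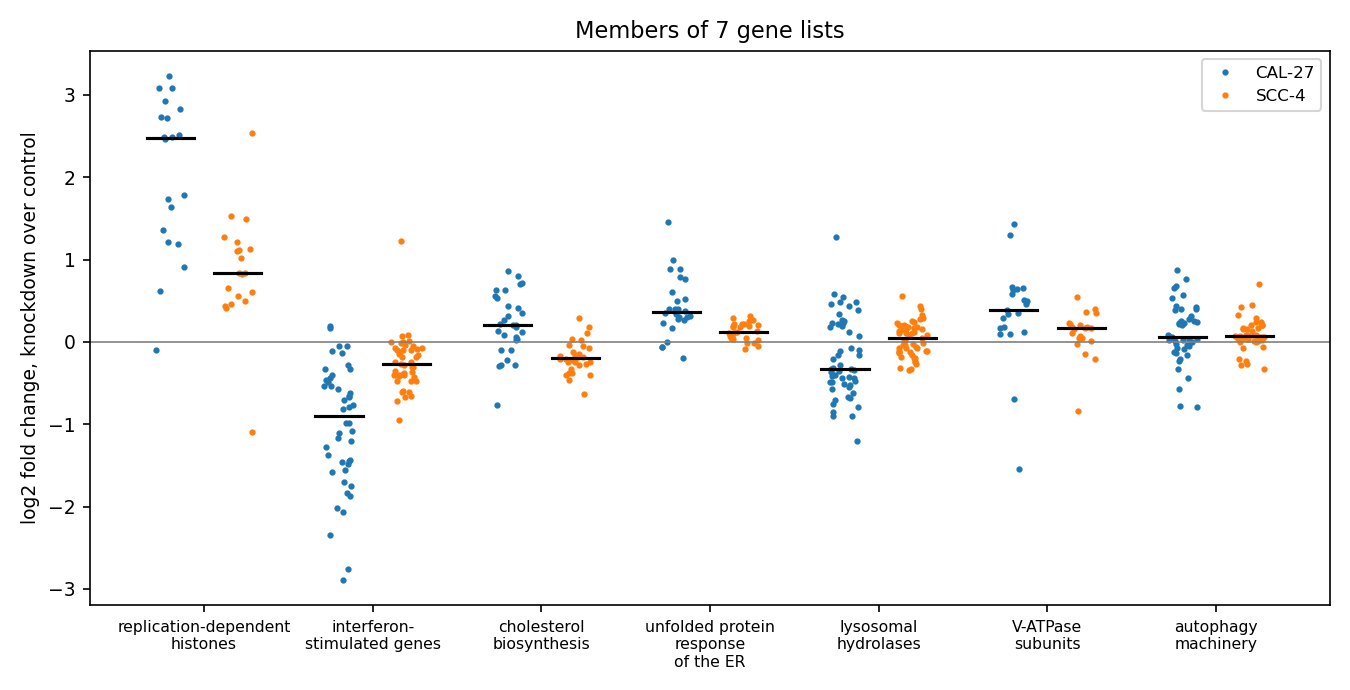
Log2 fold change, knockdown over control (y axis), of each tested member (points) of 7 gene lists (x axis) in CAL-27 (blue) and SCC-4 (orange), with black bars at the list medians. Cholesterol genes have a median of 0.21 in CAL-27 and -0.20 in SCC-4, and lysosomal hydrolases -0.33 and 0.05.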

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

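The tests on histones, on interferon-stimulated genes, on the depth of the SRSF1 fall and on the spread between replicates were chosen only after the results were seen, and those on depth, on the sign in SCC-4 and on splits of the samples were chosen before.

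The genes and lists in this part were picked because the knockdown effect differed between CAL-27 and SCC-4 by the test of the difference itself, while the third pattern and the splits within a line rest on the tests in each line. The number of genes concerned was 6239. Among 100 of the 200 possible splits of the libraries within the lines, 5 gave at least as many, the real one included, and the highest other gave 7047, so chance is not excluded by this count. The 4 other splits keep the CAL-27 arms and mix those of SCC-4, while splits that mix both lines gave at most 1 gene. A split that keeps the CAL-27 arms holds the whole CAL-27 effect.

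The first pattern is that most histone genes rose in both lines, and more in CAL-27 (median difference over the members of the list -1.357). Reads moving between near-identical tested members of the list would leave the sum of these members in place. That sum rose from 122.7 ± 0.76 to 544.9 ± 17.4 CPM in CAL-27 (log2 ratio 2.15). In SCC-4 it rose from 490.1 ± 4.77 to 818.1 ± 18.7 CPM (0.739). Gains of reads from histone genes outside the list, or of poly(A) tails, were not tested. More cells in S phase is argued against in SCC-4, where the G1/S list was called down with a median of -0.142 (bootstrap 95% interval -0.181 to -0.114; adjusted p = 0.0829 with an estimated correlation), and stays open in CAL-27, where its members went both ways (median -0.084, -0.178 to -0.00528). Carry-over of RNA without a poly(A) tail cannot be told apart from a change in histone mRNA: the 10 small RNAs of that kind had medians of 0.352 in CAL-27 (-0.699 to 0.728) and 0.0571 in SCC-4 (-0.161 to 0.326), with upper bounds below 0.5 of the histone medians (1.24 and 0.42), which goes against it, but the highest averages 1.13 CPM, too near the floor to decide. An effect of SRSF1 on histone transcripts, the biological explanation the design gives, stays untested against it.

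The second pattern is that 38 of 46 interferon-stimulated genes fell in CAL-27 and 24 in SCC-4, and by more in CAL-27 (median difference over the members of the list 0.647). Immune cells in the control cultures are argued against, since only 3 of 22 immune markers reached 5 CPM in CAL-27 controls (CD74 559, CD14 17.4 and ITGAX 5.26 CPM, scaled here by library totals), with PTPRC at 0.0233 CPM and LYZ at 0.0249 CPM. Less interferon mRNA stays open: 22 interferon genes summed to 125 counts in CAL-27 controls and 476 after knockdown, and to 470 and 477 in SCC-4, but IFNE carries most of these sums, and without IFNE they were 25 and 24 in CAL-27 and 140 and 71 in SCC-4 (exact 95% Poisson intervals 1.405 to 1.971 and 0.6776 to 1.094 CPM). An interferon response to the control construct cannot be told apart from a fall after knockdown: 0 libraries are labelled untransfected, and whether the controls, named si-NC but labelled WT, carried a construct is itself open. An effect of SRSF1 itself stays open beside it.

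The third pattern is that 10315 genes changed in CAL-27 and 4438 in SCC-4. A deeper fall of SRSF1 mRNA in CAL-27 is argued against, since the SCC-4 effect minus the CAL-27 effect was -0.0959 (95% interval -0.241 to 0.0489), and so is a smaller spread, as the coefficient of variation was 7.03% in CAL-27 and 6.48% in SCC-4. With every library thinned to 26582867 counts 10200 and 4411 genes changed, so depth does not account for it. Against a CAL-27 response wholly unrelated to that of SCC-4, 66.7% of 6871 genes called in CAL-27 alone kept their sign in SCC-4. Binomial bounds of 65.6 to 67.8% wrongly take genes as independent. Line biology and SRSF1 protein (unmeasured) stay open and untested. So do construct and batch, as arm numbers differ by line.

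Splits of the 6 libraries of a line number 10, too few for a share under 0.05. The real split gave 10315 genes, 927 beyond the study threshold and 18 lists in CAL-27, and 1 of 10 splits was as large in each case, the highest others being 1, 1 and 11. In SCC-4 it gave 4438, 113 and 14, again 1 of 10, with highest others of 1, 0 and 7. Over both lines 1 of 100 splits reached the average's 9585 genes (highest other 6707, CAL-27 arms kept). This excludes chance over libraries, not over cultures. No other split reached the lists called for the average (18, highest other 17) or the difference (18, highest other 16). Leaving out 1 library took these down to 17 and 16. The splits decide nothing for these lists or for genes called in both lines in the same direction (2992, highest other 0).

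The other lists called for the difference had these medians of the SCC-4 effect minus the CAL-27 effect over their members. They were -0.438 for cholesterol biosynthesis, 0.352 for oxidative stress (NRF2) genes, -0.191 for the unfolded protein response and 0.284 for lysosomal hydrolases. Ribosomal proteins had 0.169, YAP and TEAD targets -0.179, the SRSF1 splicing list -0.226, G2/M genes 0.179, SR proteins -0.204 and V-ATPase subunits -0.281. The inflammatory list had 0.030, the core spliceosome -0.151, heat shock proteins -0.072, NMD reporters -0.002, fibroblast markers 0.493 and the integrated stress response -0.082. With an estimated correlation 8 of these calls were lost, with adjusted p = 0.388 for ribosomal proteins and G2/M genes, 0.285 for the core spliceosome, heat shock proteins and the integrated stress response, 0.264 for NMD reporters, 0.137 for SR proteins and 0.108 for fibroblast markers.

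The named genes with the largest differences were UGT1A1 (5.482), SELENOP (3.896), ENPP5 (3.411), LOXL4 (3.277) and RCSD1 (3.273), and on the other side SERPINB2 (-3.689), EVC2 (-3.609), NAPRT (-3.352), ABCC9 (-3.219) and G0S2 (-3.169). UGT1A1 went from 21 counts to 0 over the 3 CAL-27 libraries of a group, at least 7.2-fold lower against a floor of 3 counts over the group, so its fitted value is no measured size. UGT1A1 also shares 49.9% of its exon bases with other genes. SELENOP (4 counts to 0) and EVC2 (0 counts to 4) lie near that floor in CAL-27, and NAPRT varied up to 8.83 times between replicates of a group.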

How the results depend on the processing

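Library totals with no scaling factor were the only alternative whose tests were chosen after the data were seen. No called result changed direction, while fitted values that were not called did in places, such as ATG7 in CAL-27 (from -0.1112 to 0.006692). The totals of genes or lists that moved by more than 1.5 times were these. With at least 1 CPM in 3 libraries, which tests fewer low genes, 558 genes passed the study threshold in CAL-27, 56 did in SCC-4, and 11 lists were called for the average. That SCC-4 count was 50 with DESeq2 and 61 with each line fitted alone; the cause was not tested. An estimated correlation, which allows for members moving together, left 7 lists in CAL-27, 7 in SCC-4, 5 for the average and 10 for the difference. With the replicate number as a block there were 10573, 5116, 9893 and 6748 genes for CAL-27, SCC-4, the average and the difference, 932 and 112 past the study threshold, 3441 called in both lines in the same direction, and 16, 13, 17 and 17 lists.

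Leaving out 1 library at a time gave 9373 to 10432 genes in CAL-27, 3162 to 4762 in SCC-4, 9005 to 9368 for the average and 5560 to 6054 for the difference. It gave 968 to 1051 and 98 to 129 genes past the study threshold and 2186 to 3093 genes called in both lines in the same direction. The SRSF1 log2 fold change ranged from -0.5301 to -0.4871 in CAL-27 and from -0.6391 to -0.5802 in SCC-4. Lists called numbered 17 to 19 in CAL-27, 13 to 14 in SCC-4, 17 to 19 for the average and 16 to 18 for the difference. Among list results, fibroblast markers became called in CAL-27 without CAL-27 knockdown replicate 1 (adjusted p = 0.0433) and the G1/S list without CAL-27 knockdown replicate 3 (0.0351). Of the results for named genes under these omissions 10132 kept their side of the threshold, 310 lost a call and 34 gained one.

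With library totals the median log2 fold change of all genes was -0.076 in CAL-27 and -0.032 in SCC-4, and rises made up 41.2 and 40.4% of calls. For the average 3934 genes rose and 5718 fell. Lists called up went from 13 to 7 in CAL-27 and from 12 to 6 for the average. DESeq2 size factors tilted SCC-4 the other way (2454 up and 1985 down), as did DESeq2 itself (2357 and 1888). With library totals ribosomal proteins were called down in SCC-4 (adjusted p = 0.0261) and the G1/S list in CAL-27 (0.0266). The alternatives planned for a table without counts, a pseudocount and a filter on low values, were not run because counts are given. At these depths genes below about 1 CPM carry few counts, and the counts past the study threshold depend on them most.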

Other observations

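No tests were added in this part, and the genes in it were chosen after their values were seen. NEAT1, a long noncoding RNA that builds nuclear paraspeckles, fell in CAL-27 from 2793 ± 114 to 1138 ± 87.2 CPM (log2 fold change -1.30 ± 0.08, adjusted p = 2.51e-07). In SCC-4 NEAT1 went from 1141 ± 93.2 to 958 ± 87.4 CPM (-0.25 ± 0.08, adjusted p = 0.0558), and the difference was called (1.04 ± 0.12, adjusted p = 6.34e-05). IFNE, an interferon of epithelia, rose in CAL-27 from 1.15 ± 0.240 to 5.28 ± 0.851 CPM (log2 fold change 2.20 ± 0.20, adjusted p = 7.53e-11).

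Some genes varied between replicates far more than most. Of 12352 genes at 5 CPM or more in at least 1 group, 96 had a highest replicate at least 3 times the lowest in at least 1 group, and 36 in at least 2 groups. SQSTM1 is among them, with 482, 428 and 548 counts in CAL-27 controls and 2894, 767 and 2866 in the CAL-27 knockdown. In SCC-4 SQSTM1 had 427, 407 and 1070 counts in controls and 1463, 626 and 1840 after knockdown. The largest ratio within a group was 3.63 for SQSTM1, 8.83 for NAPRT and 4.36 for PADI3.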
